A study of Mus musculus with 4 samples.

How the data were processed

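Per the labels, total RNA was extracted with a column kit from whole hearts of embryonic day 9.5 mice of a hybrid strain, amplified with amino-allyl nucleotides, coupled to Cy5 and hybridised to one-colour arrays. There were 4 arrays, 2 of control and 2 of Salv CKO pools, grouped by their titles. The deposited values are probe intensities on a linear scale, and the scanner, the background method, the scaling and the software are not given in the sources used here. The values themselves showed that the authors' intensities were background-subtracted, since 3.37 to 5.99% of the values per array lay below 0. Each array's values were whole multiples (within 0.02 of a step, 100% of values) of 1 factor per array, which was 0.891 and 0.975 for the controls and 0.973 and 1.03 for Salv CKO. As deposited, the 75th percentiles were 445 and 536 for the controls and 361 and 373 for Salv CKO, so the columns had not been brought to a common distribution. Divided by these factors, they were 499 and 550 for the controls and 370.75 and 363 for Salv CKO, and what the factors were scaled to stays unknown.

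The 4 columns were quantile normalised with limma 3.58.1 in R 4.3.3, as planned for linear values that were not yet normalised, floored at an intensity of 1 (log2 0) and put on the log2 scale. The floor was settled after the data had been seen, when fits with floors of 1, 16 and 64, with several filters on dim genes and with other splits of the arrays had been run. A floor of 16 or 64 over all genes gives many genes identical values, and so a spread of 0, and calls fewer genes; those counts are given with the other alternatives. A probe counted as above background at an intensity over 16 (log2 4), about 3 times the noise SD of 4.36 to 6.28 read from the values below 0. Of the probes, 67 to 122 per array were saturated, at an unscaled intensity of at least 65000. The number of arrays limits the precision.

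The platform's gene table, an annotation of 2013, gave 1 gene symbol for 21020 of the 29922 probes and none for 8902, which stay unnamed here. For the 3539 genes with several probes, the probe with the highest mean over all 4 arrays was used, which left 16675 genes. Of 2139 genes with at least 2 measured probes, 932 had probes of opposite sign and 8 had probes called both ways, with a median range of 0.44 (log2) between probes. Symbols were kept as in that table: 13905 are official in the RefSeq gene table of GRCm38.p6, 2766 are synonyms there and 4 were not found. The platform's table names no genome build, so no coordinates are given.

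Genes were tested with limma (lmFit and eBayes with an intensity trend, 2.92 prior degrees of freedom), two-sided, Salv CKO against control, with Benjamini-Hochberg adjustment over 16675 genes at 0.05. Gene lists, 34 with 704 of 786 genes measured, were fixed before the data were examined; 32 with at least 5 measured genes were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists). With the correlation estimated per list no list passed, at 2 residual degrees of freedom. The lowest unadjusted camera p was then 0.0311, for the neural crest list, although its estimated correlation of -0.046 lay below the preset one. For sarcomere genes the estimate was above it, at 0.019. A call lost with an estimated correlation can thus come from the few arrays and need not mean that members are correlated. A list's shift is its mean log2 difference minus that of all other genes.

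The rule for named genes was also fixed before the data were examined. It takes Sav1, the 4 genes remembered from the study of these samples, the 10 genes with the largest adjusted-significant difference in each direction with groups that did not overlap, and up to 4 members of each list past the threshold with the largest difference. Where a list had no call, the 2 members of lowest p were to be taken. Clone names and olfactory or vomeronasal receptor genes were passed over. For the 10 largest differences, genes also had to be above background on all 4 arrays, since values at the floor have no order; this was added once the values had been seen. Genes named outside the rule are marked as such where they appear.

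The procedure was tested on 20 simulations of 16675 genes with the spread of these arrays, with 200 changed genes. At an adjusted p of 0.05 it recovered 1.50% of genes changed 1.5-fold, 25.6% at 2-fold, 59.4% at 4-fold and 73.9% at 8-fold, and 4.06% of calls were false. A list of 30 genes shifted by 0.5 (log2) was found in 20 of 20 simulations, and an unshifted list in 0. Found here means an unadjusted camera p under 0.05, which is a weaker demand than the adjustment over lists used for the data. The simulated spread was drawn from limma's own fitted model without correlation between genes, and changed genes were not among the dimmest 25%. These shares therefore hold under that model and do not test it. They also hold for few changed genes, while the data gave 1772 calls. The Benjamini-Hochberg cutoff is stricter when fewer genes change, so the recovered shares do not carry over to these data. Alternatives covered the scaling, an offset of 50, the floor, filters on the dimmest 25 and 50% of probes, the mean of a gene's probes, the spread model, array weights, the replicate number as a block, the thresholds, the set test and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.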

Results

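Hearts of mouse embryos at embryonic day 9.5 were profiled on 4 one-colour oligonucleotide arrays, each hybridised with Cy5-labelled RNA amplified from a pool of whole hearts. Of these pools, 2 were controls, labelled wild-type, and 2 were Salv CKO, hearts with a conditional knockout of Salvador (Sav1), the scaffold protein that joins the Mst kinases to the Lats kinases in the Hippo pathway. The pools are described as biological replicates; how many hearts each held is not given in the sources used here. The comparison asked which genes depend on the Hippo pathway while the heart forms. Each array carried 29922 probes, and 16675 genes were tested with 1 probe each. Median deposited intensities were 77.5 and 101 on the control arrays and 71.1 and 76.1 on the Salv CKO arrays. On log2 intensities over all probes, Pearson's r was 0.946 between the controls, 0.947 between the Salv CKO arrays, and 0.937 to 0.942 across the groups. Over probes above background, differences between arrays had an SD of 0.44 and 0.42 (log2) within the groups and of 0.61 to 0.65 across them. All differences below are log2 intensity in Salv CKO minus control after quantile normalisation, with the standard error from limma and n = 2 pools per group.

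Sav1 itself (probe mMC003447) was at log2 9.43 ± 0.18 (SD, n = 2) in the controls and 9.16 ± 0.04 (SD, n = 2) in Salv CKO. The difference of -0.27 ± 0.13 did not pass the test (limma adjusted p = 0.266), although both Salv CKO pools lay below both controls. With the values as deposited the difference was -0.72 (adjusted p = 0.0199), where the median over measured genes was itself -0.44. The place of the probe relative to the deleted part of the gene is not given in the sources used here, so this value does not check the labels.

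In the Salv CKO pools 6 of 21 neural, 7 of 20 neural crest, 4 of 16 somite and 6 of 24 endoderm genes rose, and 13 of 30 sarcomere, 7 of 25 endothelial and 4 of 19 red cell genes fell, with at most 1 member of each list called the other way. As groups these lists passed camera at a preset correlation (adjusted p of at most 0.0219). None did with the correlation estimated (camera adjusted p = 0.225 to 0.273). At 2 residual degrees of freedom that version passed no list at all, so it says little about these lists in particular. Neurog2, a proneural transcription factor, rose 21.0-fold, and Sox2, a transcription factor of neural and endodermal progenitors, rose 13.04-fold. The cardiac transcription factors Nkx2-5 and Gata4 fell by 1.61 and 1.19 on the log2 scale. In all, 821 genes were higher and 951 lower in Salv CKO at a limma adjusted p under 0.05, of which 265 and 171 differed by at least 2-fold. Of these genes, 800 and 940 were above background on all 4 arrays. Over all genes the groups did not overlap for 54.2%, against 33.3% by chance. With 2 pools per group an exact permutation test of 1 gene cannot go below p = 0.333, so the calls rest on the spread that limma shares across genes. No gene passed when any 1 array was left out (3170 to 3428 genes at an unadjusted p under 0.05, against 4460 with all arrays) or when the dependence of the spread on intensity was not modelled (3578).

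The share of calls that were higher depended on the scaling: 46.3% after quantile normalisation, 22.8% with each array centred on its median, 41.3% with each divided by its 75th percentile and 6.89% with the values as deposited. The median difference over the 12402 genes above background on all arrays was -0.04, -0.17, -0.03 and -0.44 in that order.

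The 4 genes that the study of these samples had named, and which were listed from knowledge of it, all rose; as the study chose them on these samples, this is not independent evidence of their direction. Sox2 (mMC023778) went from 6.85 ± 0.36 (SD, n = 2) to 10.56 ± 0.23 (SD, n = 2), a difference of 3.71 ± 0.22 (limma adjusted p = 0.00661). Snai2, a transcription factor of epithelial-mesenchymal transition, rose by 1.30 ± 0.12 (adjusted p = 0.0102). Birc2, an inhibitor of apoptosis, rose by 1.10 ± 0.20 (adjusted p = 0.0338) on its brightest probe, while its other probes gave -0.21 and -0.39. Birc5 (survivin), which acts in apoptosis and in chromosome segregation, rose by 0.42 ± 0.07 (adjusted p = 0.0331), with 0.08 and 0.17 on its other probes and -0.07 for the gene with the values as deposited. Adjusted over the list alone, 4 of 4 passed as well.

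Among genes above background on all 4 arrays, the largest rises were of Nepn, a small leucine-rich proteoglycan (4.82 ± 0.64), Neurog2 (4.40 ± 0.22), the homeobox gene Nkx2-3 (4.18 ± 0.26), Sox2, and the claudin Cldn11 (3.51 ± 0.33). They were followed by Fez1, which acts in axon growth (3.38), the somite transcription factor Tcf15 (3.08), the forkhead gene Foxd1 (2.96), Serinc4 (2.92) and the neuronal stathmin Stmn3 (2.92). Their limma adjusted p lay between 0.00439 and 0.0180. The other probe of Nkx2-3 gave 1.37 ± 0.51 with no call (adjusted p = 0.216), and that of Sox2 gave 2.94. One control pool held Nepn near the background limit, at an intensity of 16.4 against 63.4 in the other. Control intensities were also near it for Cldn11 (17.4 and 28.2) and Nkx2-3 (17.4 and 22).

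The largest falls were of Baz2a, a subunit of the complex that silences ribosomal RNA genes (-2.45 ± 0.13), Rai1 (-2.35 ± 0.19), the glucose transporter Slc2a12 (-2.21 ± 0.33), the cadherin Cdh20 (-2.21 ± 0.32) and the lymphocyte surface protein Cd7 (-2.13 ± 0.38). Next came the collagen Col8a1 (-1.997), the small Maf protein Mafk (-1.95), the GPI transamidase subunit Pigs (-1.87), the muscle filamin Flnc (-1.79) and Lrrc4b (-1.76). Limma adjusted p ranged from 0.00640 to 0.0364. Of these genes Rai1, Cdh20, Col8a1 and Flnc had another probe each, which gave -0.30, -0.85, -0.42 and 0.36 with no call. The Salv CKO pools held Slc2a12 near the background limit, at intensities of 19.1 and 20.3. Among the genes above background on all arrays, 44 rose and 5 went down at least 4-fold.

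**Figure D1:**
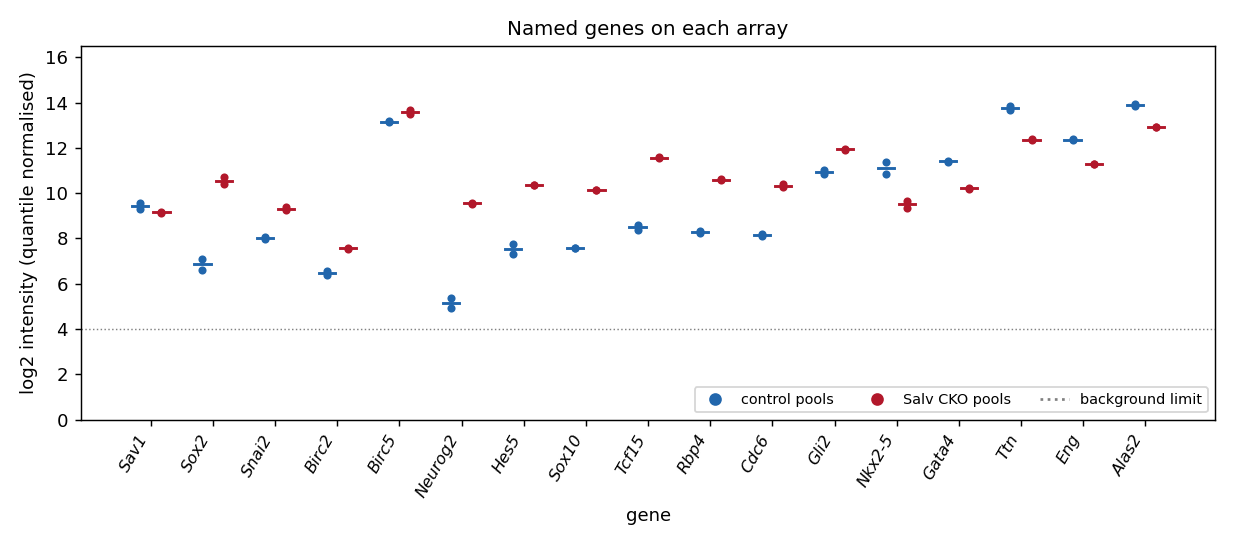
Log2 intensity after quantile normalisation (y axis) of 17 named genes (x axis) on each array, with control pools in blue, Salv CKO pools in red, group means as bars and the background limit of log2 4 as a dotted line. Neurog2 went from 5.15 to 9.54 and Sox10 from 7.58 to 10.15, while Nkx2-5 went from 11.11 to 9.504; Birc5 was higher here by 0.42, and by -0.07 with the values as deposited.

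Of 21 measured neural genes, 6 rose and 1 fell, and 8 and 1 did when adjusted over the list alone. Next to Sox2 and Neurog2, Hes5, a Notch effector of neural progenitors, rose by 2.83 ± 0.17 (adjusted p = 0.00661). Zic1, a transcription factor of the dorsal neural tube, was at 12.10 ± 0.15 in Salv CKO, while 1 of the 2 control arrays held it above background (adjusted p = 0.0194). The member that fell, named after its value was seen, was Nes, an intermediate filament of progenitors (-0.75 ± 0.10). Among those not called, Tubb3 and Elavl3, genes of postmitotic neurons picked after their values were seen, gave 0.49 (adjusted p = 0.0770), near the list's median of 0.55, and -0.18 (adjusted p = 0.678). The list lay 1.32 above the other genes (camera adjusted p = 0.000280; adjusted p = 0.225 with an estimated correlation).

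Neural crest and pharyngeal genes moved up in the same pools, with 7 of 20 that rose and 0 that fell (10 and 0 adjusted over the list alone). The crest transcription factors Sox10 and Pax3 rose by 2.57 ± 0.11 and 2.14 ± 0.28, Tcfap2b rose by 2.73 ± 0.26, and Crabp1, a retinoic acid binding protein, rose by 1.82 ± 0.06. The list's median was 0.89, and 0.49 with members at background entered at their bound or at 0. Its shift was 1.25 (camera adjusted p = 6.1e-06, and 0.225 with an estimated correlation), and 0.68 to 1.37 over all alternatives.

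Of 16 somite and skeletal muscle genes 4 rose and 1 fell (7 and 1 adjusted over the list alone). The risen genes included Tcf15, Meox1 (2.50 ± 0.20) and Uncx (2.41 ± 0.32), all of early somites, and the fallen gene was the muscle creatine kinase Ckm (-1.40 ± 0.22). The median was 0.96 and the shift 0.88 (camera adjusted p = 0.0219; adjusted p = 0.273 with an estimated correlation). The call was lost without control pool 1 (0.52, adjusted p = 0.0946), Salv CKO pool 1 (0.89, adjusted p = 0.0820) or Salv CKO pool 2 (0.87, adjusted p = 0.0889) and with all genes floored at 64 (0.46, adjusted p = 0.0537).

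Endoderm, liver and yolk sac genes gave 6 of 24 that rose and 0 that fell (10 and 1 adjusted over the list alone). The retinol carrier Rbp4 rose by 2.31 ± 0.10, alpha-fetoprotein (Afp) by 1.56 ± 0.16, the tight junction gene Cldn6 by 1.39 ± 0.15 and the foregut factor Foxa1 by 1.35 ± 0.13. Their median was 0.56 (camera adjusted p = 0.000232; adjusted p = 0.225 with an estimated correlation). The medians of these 4 lists stayed above 0 under each scaling, and were lowest with the values as deposited (0.27, 0.47, 0.68 and 0.18).

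**Figure D2:**
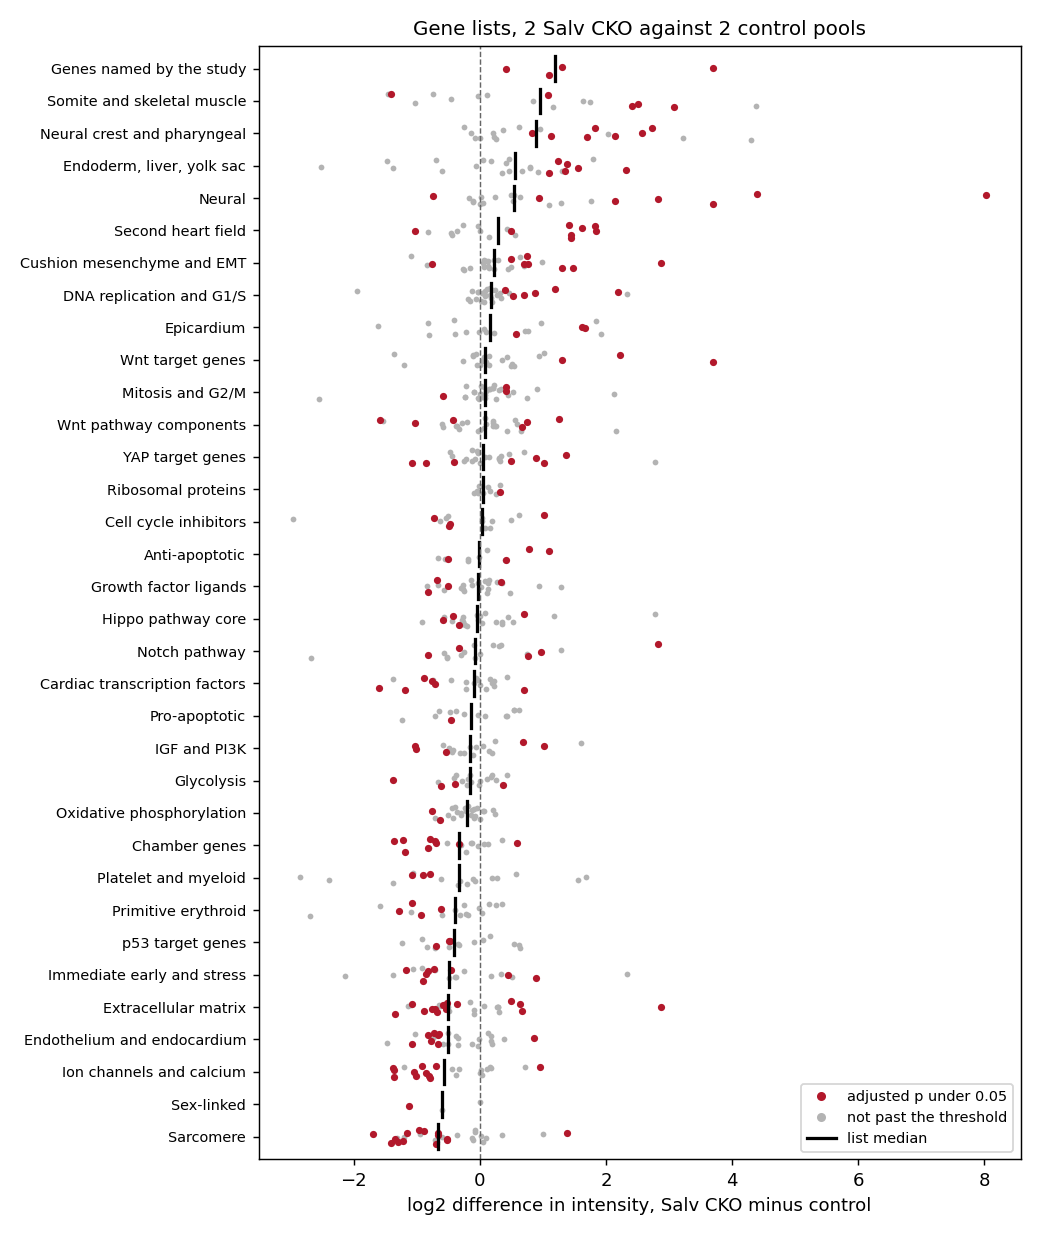
Log2 difference in intensity, Salv CKO minus control (x axis), of each measured gene in 34 gene lists (y axis), with genes at an adjusted p under 0.05 in red, other genes in grey and each list's median as a black bar. Medians ran from -0.67 for the sarcomere list to 1.20 for the 4 genes named by the study; those of second heart field, cushion, replication and Wnt target genes were above 0 here and below 0 (-0.17, -0.20, -0.32 and -0.22) with the values as deposited.

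Sarcomere genes were lower as a group: 13 of 30 fell and 1 rose (18 and 2 adjusted over the list alone). Xirp1, an actin-binding protein of heart muscle, fell by 1.69 ± 0.08 on the log2 scale, titin (Ttn) by 1.41 ± 0.09 and telethonin (Tcap) by 1.35 ± 0.07, while the tropomyosin Tpm1 rose by 1.39 ± 0.11. The median was -0.67 (camera adjusted p = 3.3e-06; adjusted p = 0.225 with an estimated correlation), in the same pools in which the neural and neural crest lists lay 1.32 and 1.25 above the other genes.

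Genes of cardiac ion channels and calcium handling went down as well, with 10 of 22 that fell and 1 that rose (13 and 1 adjusted over the list alone). The T-type calcium channel Cacna1h fell by 1.38 ± 0.10, phospholamban (Pln) by 1.36 ± 0.18 and the potassium channel Kcnq1 by 1.04 ± 0.11 (-0.12 ± 0.17 on its other probe). The gap junction gene Gja5 fell by 1.36 ± 0.13 on its brightest probe and was at 0.24 as the mean of its probes, of which the other had a mean below the background limit (1.83 ± 1.38). Of 20 chamber genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), among them the ventricular factor Irx4 (-1.22 ± 0.09), the neuregulin receptor Erbb2 (-1.18 ± 0.09) and the natriuretic peptide Nppb (-0.83 ± 0.08). The list shifts were -0.46 and -0.41 (camera adjusted p = 0.000473 and 0.000475; adjusted p = 0.225 with an estimated correlation for each).

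Of 21 cardiac transcription factors 5 fell and 1 rose, and the counts were the same when adjusted over the list alone. Besides Nkx2-5 (-1.61 ± 0.21) and Gata4 (-1.19 ± 0.08), Smyd1 fell by 0.89 ± 0.12 (-0.19 ± 0.20 on its other probe) and Gata5 by 0.77 ± 0.14. The list as a whole did not pass (shift -0.29, camera adjusted p = 0.103), though it did with each array centred on its median (-0.41, adjusted p = 0.0162) and under 4 of 21 alternatives in all (0.00440 to 0.332). Medians of all of these heart muscle lists lay below 0 under each scaling.

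Endothelial and endocardial genes were lower too: 7 of 25 fell and 1 rose (11 and 1 adjusted over the list alone). Endoglin (Eng) fell by 1.08 ± 0.07, Plvap by 0.82 ± 0.08 and VE-cadherin (Cdh5) by 0.77 ± 0.09, whereas the claudin Cldn5 rose by 0.86 ± 0.12. Of 19 primitive red cell genes 4 fell and 0 rose (5 and 0 adjusted over the list alone), including the haem synthesis enzyme Alas2 (-0.94 ± 0.07) and the embryonic globin Hbb-y (-1.08 ± 0.20). The shifts were -0.37 and -0.57 (camera adjusted p = 0.00119 and 0.00171; adjusted p = 0.225 with an estimated correlation for both). The endothelial list did not pass with fry (adjusted p = 0.0879). Of 18 platelet and myeloid genes 3 fell, among them the platelet integrin Itga2b (-0.91 ± 0.14) and platelet factor 4, listed as Cxcl4 (-1.07 ± 0.17), and 5 fell when adjusted over the list alone. That list did not pass (camera adjusted p = 0.0602), but did under 8 of 21 alternatives (adjusted p = 0.00415 to 0.587), and its shift of -0.42 ranged with 1 array left out from -0.63 (without Salv CKO pool 1, called) to -0.22 (without Salv CKO pool 2, not called).

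Of the 27 measured Hippo pathway components 1 rose and 3 fell (2 and 6 adjusted over the list alone). The kinase Mst1 (Stk4) fell by 0.33 ± 0.06, the cadherin Dchs1 by 0.58 ± 0.11 and the Tead cofactor Vgll4 by 0.43 ± 0.09. Mobkl1b, the Lats cofactor Mob1a, rose by 0.70 ± 0.11 on its brightest probe and was at -0.33 as the mean of its probes, of which the other had a mean below the background limit (-1.37 ± 1.26). The list did not shift against other genes (0.07, and -0.06 to 0.19 over all alternatives, camera adjusted p = 0.423). Camera placed it down, against its positive mean, and its median was -0.04. The mean includes Jub, named after its value was seen, at 2.77 ± 1.11 with both control arrays at or below the background limit.

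Genes known as targets of Yap, the coactivator that the pathway restrains, went both ways: 4 of 26 rose and 3 fell (5 and 3 adjusted over the list alone). The forkhead gene Foxf2 rose by 1.36 ± 0.15, the Hedgehog effector Gli2 by 1.02 ± 0.09 (-0.05 ± 0.14 on its other probe) and the kinase Nuak2 by 0.88 ± 0.10, and the focal adhesion protein Tgfb1i1 fell by 1.08 ± 0.17. The list shift was 0.21 (camera adjusted p = 0.236), and 0.06 to 0.36 with 1 array left out, beside 1.25 for the neural crest list. Its median of 0.04 was -0.01 with each array centred on its median and -0.28 with the values as deposited. The shift is a mean that includes Jub, named after its value was seen, at 2.77 ± 1.11 with both control arrays at or below the background limit. The 3 targets most often used as readouts, picked after their values were seen, did not rise: Ctgf fell by 0.41 ± 0.08 (adjusted p = 0.0453), Cyr61 was at 0.15 (adjusted p = 0.473) and Ankrd1 at -0.08 (adjusted p = 0.784). Ankrd1 also stands in the sarcomere list, whose median was -0.67. In pooled whole hearts these values do not show Yap activity within heart muscle cells.

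Of 27 Wnt target genes 3 rose and 0 fell (5 and 0 adjusted over the list alone). These were Sox2, Snai2 and Sfrp2, a secreted Wnt modulator (2.22 ± 0.10, adjusted p = 0.00615). Sox2 and Snai2 were among the genes the study had named on these samples, so their part in this list is not independent evidence, and Sox2 also stands in the neural list, whose shift was 1.32. The Wnt target list lay 0.35 above the other genes (camera adjusted p = 0.00919; adjusted p = 0.225 with an estimated correlation), and 0.18 above them without Sox2 and Snai2 (camera adjusted p = 0.0602). Its median was 0.09, and -0.22 with the values as deposited. Axin2 and Lef1, widely used readouts chosen after their values were seen, were at -0.05 (adjusted p = 0.920) and 0.15 (adjusted p = 0.696). Of 29 Wnt pathway components 3 rose and 3 fell (4 and 5 adjusted over the list alone): the receptor Fzd7 (1.25 ± 0.09) and the antagonist Sfrp1 (0.75 ± 0.10) rose, the ligands Wnt1 (-1.59 ± 0.22) and Wnt11 (-1.03 ± 0.09) fell, and the list did not shift (0.05, camera adjusted p = 0.571).

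DNA replication and G1/S genes were shifted up by 0.29, with 6 of 32 that rose and 0 that fell, also when adjusted over the list alone (camera adjusted p = 0.000880; adjusted p = 0.225 with an estimated correlation). The origin licensing factor Cdc6 rose by 2.20 ± 0.11 (2.26 and 0.11 on its other probes), the cyclin Ccne2 by 1.20 ± 0.12 (0.48 on its other probe), the polymerase subunit Pola1 by 0.87 ± 0.12 and Orc6l by 0.70 ± 0.08. The list's median of 0.17 was -0.05 with each array centred on its median and -0.32 with the values as deposited, and the shift was then 0.19 with each (camera adjusted p = 0.0835 and 0.718; 0.000125 to 0.718 over its alternatives). The neural and neural crest lists lay 1.32 and 1.25 above the other genes in these pools (0.91 to 1.54 and 0.68 to 1.37 over all alternatives). Of 33 mitosis and G2/M genes 2 rose and 1 fell (0 and 0 adjusted over the list alone): Birc5 and the checkpoint gene Mad2l1 (0.41 ± 0.08, and -0.10 with the values as deposited) rose, the kinesin Kif2c fell by 0.58 ± 0.12, and the list did not pass (0.13, camera adjusted p = 0.146). Of 15 cell cycle inhibitor genes 1 rose and 3 fell (1 and 4 adjusted over the list alone). Btg1 rose by 1.01 ± 0.07, Btg2, Cdkn1a and Ccng1 fell by 0.72, 0.49 and 0.47, the other probe of Ccng1 gave 0.40 ± 0.09 with no call, and the list did not pass (camera adjusted p = 0.718).

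Anti-apoptotic genes gave 3 of 11 that rose and 1 that fell (4 and 3 adjusted over the list alone). Besides Birc2 and Birc5, Bcl2 rose by 0.77 ± 0.09 on its brightest probe and was at -0.50 as the mean of its probes. Its other probes gave -0.23 and -0.46 and, with a mean below the background limit, -2.06 ± 1.00. Bcl2l1 fell by 0.50 ± 0.10 (0.31 ± 0.25 on its other probe), and the list did not pass (0.08, camera adjusted p = 0.480). Of 14 pro-apoptotic genes 1, the effector Bak1, fell by 0.46 ± 0.09, and 0 passed when adjusted over the list alone (camera adjusted p = 0.645).

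Second heart field genes, of the progenitors added at the poles of the heart, gave 7 of 18 that rose and 1 that fell, also when adjusted over the list alone. Crabp2 rose by 1.84 ± 0.14, Crabp1 by 1.82, the retinoic acid synthesis enzyme Aldh1a2 by 1.61 ± 0.11 and Hoxb1 by 1.45 ± 0.12. Of 28 cushion mesenchyme genes 7 rose and 1 fell (9 and 3 adjusted over the list alone), led by periostin (Postn, 2.87 ± 0.36), decorin (Dcn, 1.48 ± 0.21), Snai2 and Sox9 (0.76 ± 0.10). The shifts were 0.45 and 0.36 (camera adjusted p = 0.00850 and 0.00119; adjusted p = 0.225 with an estimated correlation for both), beside the neural crest list's 1.25. Without Salv CKO pool 2 the second heart field call was lost (0.44, adjusted p = 0.0585). The cushion call was lost with the values as deposited (0.24, adjusted p = 0.215). The medians of both lists, 0.29 and 0.22, were -0.17 and -0.20 with those values, and 0.07 and 0.22 with members at background entered at their bound or at 0. Of 18 epicardial genes 3 rose and 0 fell (6 and 1 adjusted over the list alone), namely Aldh1a2, Sema3d (1.66 ± 0.17) and Upk3b (0.58 ± 0.10, and -0.13 ± 0.13 on its other probe). The list did not pass (camera adjusted p = 0.0738), but did under 7 of 21 alternatives (adjusted p = 0.0182 to 0.332), and its shift of 0.36 was 0.14 without control pool 2, 0.57 without control pool 1, 0.16 without Salv CKO pool 2 and 0.55 without Salv CKO pool 1. Of 29 extracellular matrix genes 10 fell and 4 rose (15 and 4 adjusted over the list alone): Col6a2 (-1.35 ± 0.23) and the basement membrane collagens Col4a1 (-1.08 ± 0.10) and Col4a2 (-0.89 ± 0.10) fell, and the list's shift was -0.23 (camera adjusted p = 0.0163; adjusted p = 0.284 with an estimated correlation), and -0.21 with no call without Salv CKO pool 1 (adjusted p = 0.0820).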

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

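The tests of trunk Hox genes, of uniform dilution and of a lower share of heart muscle cells were chosen only after the results were seen; the other tests were set before their values were seen, when the list results and the counts under each scaling were already known.

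Probes that carry no gene name here take no part in the comparison of genes, and 160 of these 8902 probes were higher in Salv CKO than in the controls (limma adjusted p under 0.05), with 102 lower. Of the unnamed probes 4473 were above background on all arrays. The largest rises among those were mMC008430 (4.03 ± 0.23) and mMC025312 (3.60 ± 0.28), and the largest falls mMC012470 (-3.56 ± 0.35) and mMC020262 (-3.26 ± 0.20).

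The first pattern is that neural, crest, somite and endoderm genes were higher in both Salv CKO pools. A candidate explanation is more tissue from next to the heart in those dissections, which second marker lists tested: other neural tube genes had a median of 0.40 (40 genes, camera p = 0.00242; p = 0.0701 with an estimated correlation), epithelial and foregut genes 0.77 (26 genes, p = 1.1e-06; p = 0.0320 with an estimated correlation) and trunk Hox genes 0.63 (30 genes, p = 0.000313; p = 0.0599 with an estimated correlation), which go with it. Other paraxial mesoderm genes left it open, with a median of 0.39 (22 genes, camera in limma, p = 0.0801; p = 0.268 with an estimated correlation). Within the neural list Nes, named after its value was seen, went the other way (-0.75). Some called members of the second lists did so too. Irx2 fell (-0.34) against 6 neural tube genes that rose. Col2a1 (-1.37) and Cited4 (-1.002) fell against 2 paraxial mesoderm genes that rose. A change of these genes within the mutant heart stays open and untested, since in pooled whole hearts it cannot be separated from a change of tissue by these values.

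The second pattern is that heart muscle genes were lower. Dilution by other tissue to the same degree for every muscle gene would leave differences that vary little beyond their standard errors. Over 23 measured, unsaturated sarcomere genes the differences had an SD 5.55 times their median standard error, from -1.69 for Xirp1 to 1.39 for Tpm1. An equal fall of all these genes is thus not the whole pattern. The test was chosen once these values were known. It assumes added tissue without these transcripts and probes that respond alike, so it cannot exclude unequal dilution. A lower share of heart muscle cells alone would raise the other cell types of the heart alike, and these lists did not move alike. The endothelial list shifted by -0.37 (-0.47 to -0.28 over all alternatives), while cushion mesenchyme shifted by 0.36 (0.24 to 0.39). Second heart field shifted by 0.45 (0.36 to 0.62) and epicardium by 0.36 with no call (0.14 to 0.57). Aldh1a2 stands in both of these lists, and Crabp1 in the second heart field and the neural crest list. Their rises are therefore not separate from each other or from the first pattern. The red cell list shifted by -0.57 (-0.60 to -0.31), but blood in the pools need not follow the share of muscle. The endothelial fall goes against a lower muscle share as the whole cause, though these shifts were known when the test was chosen. The calls among these are lost with an estimated correlation (adjusted p = 0.225), the endothelial one also with fry (0.0879) and the cushion one as deposited (0.215). Other tissue together with a change of heart genes in the mutant may both contribute, and the loss of Salvador itself remains among the open explanations, untested.

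The third pattern is that the split of higher against lower genes moved with the scaling. If 1 brightness factor per array were the cause, dim and bright genes would differ alike between the groups in the deposited values. Their medians were -0.31, -0.42, -0.51 and -0.51 from the dimmest to the brightest 25% of genes, and the outer ones differed by 0.199, which lay between the bounds set for and against it. Whether the lower brightness of the Salv CKO arrays came from labelling, scanning or less of most RNAs cannot be told apart here, as both arrays of the group share it.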

How the results depend on the processing

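The values as deposited, the 75th percentile scaling, the floors of 16 and 64, the restriction to genes above background and the Wnt list without Sox2 and Snai2 were chosen after seeing the data. The main counts were 821 higher and 951 lower. They became 2093 and 2367 at an unadjusted p under 0.05, 1386 and 1579 at an adjusted p under 0.10, 541 and 1830 with each array centred on its median, and 229 and 3096 with the values as deposited. Dividing each array by its 75th percentile gave 991 and 1406. The mean of each gene's probes gave 558 and 666, of which 493 and 649 were also called that way in the main fit. With that mean 1703 of the 1772 main calls kept their sign. Fewer genes tested gave 1272 and 1490 without the dimmest 50% of probes and 1239 and 1437 over genes above background on all arrays. All genes floored at 16 gave 253 and 229, and at 64 gave 259 and 234, where many genes have no spread; with genes at the floor of 16 on all arrays left out the counts were 870 and 1005. Without the intensity trend limma called 0 and 0 genes (3578 at an unadjusted p under 0.05), and with any 1 array left out 0 to 0 higher and 0 to 0 lower (3170 to 3428), where the lone pool of a group is assumed to vary like the others. The 2 other splits of the 4 arrays gave 0 calls each, with 438 and 252 genes at an unadjusted p under 0.05, against 1772 and 4460; 3 splits are too few to judge chance.

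The main fit did not pair the pools by their numbers 1 and 2. Deviations of same-numbered pools correlated weakly, at 0.0259 over all probes and 0.147 over those above background. With the replicate number as a block the counts were 1016 and 1195. An effect shared by same-numbered pools is not excluded.

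Sav1 was -0.72 with the values as deposited (adjusted p = 0.0199; 0.122 to 0.515 under the others) and -0.40 to -0.14 with 1 array left out. The sarcomere shift of -0.53 lost its call only with an estimated correlation (adjusted p = 0.225; at most 0.00053 with 1 array left out). So did the replication shift of 0.29, which also lost it at 0.19 with each array centred on its median (adjusted p = 0.0835) and at 0.19 as deposited (0.718). The Wnt target shift of 0.35 lost it with an estimated correlation (0.225), with fry (0.137) and at 0.18 without Sox2 and Snai2 (0.0602). Over all alternatives the adjusted p ran from 2.4e-07 to 0.225 for sarcomere, 0.000125 to 0.718 for replication and 0.00455 to 0.225 for Wnt target genes. Yap target, mitosis and anti-apoptotic lists passed under no alternative, with shifts of 0.06 to 0.36, 0.05 to 0.20 and 0.02 to 0.14 with 1 array left out, and no list call reversed. With the mean of a gene's probes, Bcl2 (-0.50), Gpi1 (-0.0894) and Pfkm (0.18) changed sign, where other probes above background went the other way. The mean for Bcl2 also holds a probe at -2.06 ± 1.00 with a mean below the background limit. Foxo3 (-0.54), Gja5 (0.24), Mobkl1b (-0.33) and Ppargc1a (0.52) changed sign too, and their other probe had a mean below the background limit. As deposited, Birc5 (-0.0708), Gpi1 (-0.0807), Mad2l1 (-0.10), Rpl23 (-0.14) and Vegfc (-0.17) changed sign, with no call. Where no construction is named, the cause was not tested. Signal over background limits 1873 genes, at or below the limit in both groups.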

Other observations

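The lists of trunk Hox genes and the genes singled out from the second marker lists were chosen only after results were seen; the other second marker lists were written after the main results but before their own values were seen, and the fixed lists before the data were examined.

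Notch pathway genes went both ways, with 3 of 19 that rose and 2 that fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.645). The effectors Hes5 (2.83) and Hes1 (0.76 ± 0.08) and the glycosyltransferase Mfng (0.98 ± 0.12) rose. The endothelial ligand Dll4 fell by 0.82 ± 0.12, and by less on its other probe (-0.23 ± 0.22, with no call). Of 25 growth factor genes 1 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.480), with Bmp7 at -0.69 ± 0.08 and Vegfb at -0.50 ± 0.08, and with Vegfc at 0.34 ± 0.07 after quantile normalisation and at -0.17 as deposited. Of 19 genes of IGF and PI3 kinase signalling 2 rose and 3 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.310). The kinase Akt1 fell by 1.03 ± 0.16, the receptor Igf2r by 1.01 ± 0.19 and Igfbp2 rose by 0.68 ± 0.08, while Foxo3 was at 1.01 ± 0.13 on its brightest probe and at -0.54 as the mean of its probes, of which the other had a mean below the background limit (-2.09 ± 1.29).

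Genes of oxidative phosphorylation were shifted by -0.22, with 2 of 24 that fell and 0 that rose, also when adjusted over the list alone (camera adjusted p = 0.00919; adjusted p = 0.308 with an estimated correlation). With the mean of each gene's probes the shift was -0.12 with no call (camera adjusted p = 0.0579). The sarcomere list's shift in the same pools was -0.53. The complex III subunit Uqcrc1 fell by 0.63 ± 0.12, and the coactivator Ppargc1a was at -0.76 ± 0.11 on its brightest probe and at 0.52 as the mean of its probes, of which the other had a mean below the background limit. Of 19 glycolysis genes 3 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.373). The hexokinase Hk1 (-1.37 ± 0.19) and the muscle enolase Eno3 (-0.39 ± 0.08) fell, Pfkm was at -0.61 ± 0.11 and at 0.18 as the mean of its probes, and Gpi1 at 0.37 ± 0.06, at -0.09 as the mean of its probes and at -0.08 as deposited.

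Among signs of RNA handling, immediate early and stress genes were shifted by -0.37, with 6 of 21 that fell and 2 that rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0261; adjusted p = 0.273 with an estimated correlation). That call was lost without control pool 1 (-0.35, adjusted p = 0.0919) or Salv CKO pool 1 (-0.12, adjusted p = 0.204), without the intensity trend (adjusted p = 0.0547) and with the values as deposited (-0.40, adjusted p = 0.0794), and the shift was -0.61 without Salv CKO pool 2. Jund fell by 1.17 ± 0.08, Fos by 0.90 ± 0.11 and Zfp36 by 0.85 ± 0.11, and Socs3 rose by 0.90 ± 0.16. Of 11 ribosomal protein genes 1, Rpl23, was called, at 0.33 ± 0.07, and at -0.14 as deposited (1 adjusted over the list alone; camera adjusted p = 0.146). Of 16 p53 target genes 3 fell and 0 rose (3 and 1 adjusted over the list alone), among them Zmat3 (-0.69 ± 0.13), and the list did not pass (camera adjusted p = 0.104), but did under 1 of 21 alternatives, with its shift of -0.28 at -0.46 without Salv CKO pool 2 (called), -0.10 without Salv CKO pool 1 and -0.14 without control pool 1 (adjusted p = 0.0445 to 0.485 over all alternatives). Of 3 measured sex-linked genes the Y-linked Eif2s3y fell by 1.12 ± 0.12 (limma adjusted p = 0.0122). Adjusted over the list alone 2 fell, and 0 of the 3 had a positive difference. The sex of the pooled embryos is not given in the sources used here, so whether the groups differed in sex make-up stays open and was not tested.

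The second marker lists behind the hypothesis of neighbouring tissue in the Salv CKO dissections shared 0 genes with the fixed lists and held 0 of the genes the study named. Among 30 trunk Hox genes 7 rose and 0 fell, with Hoxb5 at 1.93 ± 0.12, Hoxa7 at 2.36 ± 0.32 and Hoxb9 at 2.78 ± 0.40. Hoxc12 and Hoxc4, which had the brightest probes of the list, though brightness does not rank genes by abundance, were at 0.12 (adjusted p = 0.425) and 0.05 (adjusted p = 0.790). Of 26 epithelial and foregut genes 8 rose and 0 fell, led by Rbm35a (Esrp1, an epithelial splicing factor) at 1.40 ± 0.12 and the junction gene Cgn at 1.20 ± 0.10, while Cldn4 was at 0.18 (adjusted p = 0.322). Of 40 neural tube genes 6 rose and 1 fell, with Sox11 at 1.07 ± 0.08, Dll3 at 1.54 ± 0.14 and Irx2 at -0.34 ± 0.07. Of 22 paraxial mesoderm genes 2 rose and 2 fell, with Pdgfra at 0.86 ± 0.08, Col2a1 at -1.37 ± 0.10 and Cited4 at -1.002 ± 0.14. In both controls 32 of the 40 neural tube, 13 of the 22 paraxial, 18 of the 26 epithelial and 18 of the 30 Hox genes were above background already, as were 18 of the 21, 17 of the 20, 12 of the 16 and 20 of the 24 genes of the fixed neural, crest, somite and endoderm lists. Of these fixed lists 4, 2, 0 and 1 genes stand in another list, and 1 neural gene, Sox2, was named by the study.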
